A study of Mus musculus with 7 samples.

How the data were processed

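The deposited files held 1 table per muscle, with 1 column per cryosection of mouse tibialis anterior. Per the labels, 2 muscles were WT, 2 were Ctr and 3 were DMD. The unit, per the file headers, was expected counts: reads per gene and section in which multi-mapped and multi-overlapping reads had been divided into fractions, so 20.1 to 26.1% of the nonzero values were not whole. Per the submitters' processing notes, reads had been aligned with STAR 2.7.7a to GRCm38. Per the file headers, reads had been counted with featureCounts 2.0.1 (options -M -O --fraction -s 1, exons summed by gene name). Per the labels, the RNA was polyA RNA extracted from single sections with TRIZOL, and read 2 held an 8-base molecular identifier followed by an 8-base section barcode. The column names in the headers carry the words trimmed, homoACTG and dedup2, which the labels do not describe further.

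Per the file headers, the WT tables were counted with GRCm38 release 102 plus spike-in and EGFP sequences (55460 genes and sequences), and the Ctr and DMD tables with another GRCm38 annotation plus spike-in and human DMD sequences (54414). The analysis used the 53083 genes with 1 name and 1 length in all 7 tables. Of 53187 names in both annotations, 12 had another length and 92 were spike-ins, and these were left out, as were names in only 1 annotation. Sequences outside the shared genes were used only for the checks of dystrophin, EGFP and spike-ins. The fixed gene lists had 250 entries in 27 lists, and 1 entry (Ctgf) was not among the shared genes.

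A section was kept if its total was at least 1000 and at least 20% of the median section total of its muscle. Kept sections were added up per muscle, and each sum was rounded to whole numbers first, before any test. The muscle was the replicate in every test, and sections were never counted as replicates. No sample was left out.

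The regions were defined within each muscle from 2 fixed lists. A section score was the mean z-score of log2 (CPM plus 10) over the list. The 20% of sections with the highest tendon score formed the tendon-marker-rich region (Tnmd, Fmod, Comp, Chad, Kera, Cilp2, Scx and Mkx), and the 20% with the highest synaptic score formed the synaptic-marker-rich region (Chrne, Colq, Ufsp1, Etv5, Etv4 and Chrnd). A section in the top 20% of both went to the region with the higher score, and all others were the remaining sections. The defining genes were left out of the counts of genes called between regions. The 2 defining lists were also left out of the counts of lists called between or inside regions. Held-out lists of myotendinous junction and synaptic genes tested the regions.

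Whole-muscle comparisons used edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling (factors 0.669 to 1.41) and quasi-likelihood F tests over all 3 groups. Region comparisons fitted muscle plus region terms per group on 3 sums per muscle, with the remaining sections as the reference, and the effect was averaged over the 3 groups with equal weight or subtracted between DMD and Ctr. Comparisons of DMD with Ctr inside a region used only that region's sums. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. The ± after a log2 fold is an approximate standard error, the absolute log2 fold divided by the square root of F. The ± after a median of several genes, or after a share of genes, is a standard error over those genes taken as independent. It does not measure the spread between muscles. The ± after a CPM is the standard deviation between muscles, given with n. CPM values beside folds are TMM-scaled.

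Genes were named by rule: up to 8 called genes per direction with the largest log2 fold, a mean of at least 20 CPM and no overlap between the muscles of the groups (or 1 sign in all 7 muscles), and up to 3 members of each fixed list, called ones first by fold. A list with no called member was represented by its most highly expressed measured member. Some genes that the rule names are not reported here. Where every sample of a group had 0 counts, the fold is given as a lower bound with a floor of 3 counts over that group.

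The lists cover regenerating fibre, satellite cell, macrophage, lymphocyte, granulocyte, fibro-adipogenic progenitor, fibrotic matrix, adipocyte, endothelial, pericyte and smooth muscle, Schwann cell, erythroid, and bone, cartilage and skin genes. They also cover tendon, myotendinous junction, 2 sets of synaptic genes, slow fibre, fast fibre, oxidative phosphorylation, mitochondrially encoded, glycolysis, dystrophin complex, interferon response, proliferation, atrophy and denervation, and immediate early and heat shock genes. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, then with the correlation estimated from the samples, and with fry. These p-values were adjusted by the Benjamini-Hochberg method over the lists of a comparison. Counts adjusted over the list alone used only the list's own p-values. Camera and fry could not be run on lists with fewer than 2 measured genes.

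For the order of sections, the correlation of each list score between neighbouring sections was compared with 1000 shuffles of the order within a muscle. Unevenness of a list along the muscle was computed on sections thinned to 1 total (30384 counts, or 15192 as an alternative) and compared between muscles by exact two-sided permutation tests. Lists with a mean under 1 count per thinned section in any muscle were left out of its count. Section order followed the numbers in the column names, per the file headers, and the labels do not say which end of the muscle came first. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the sums, section statistics and figures.

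Alternatives, named before the data were examined, were DESeq2 1.42.0 size factors and Wald test, no expression filter, a mean of at least 20 CPM, all sections, sections thinned to 1 total before summing, only the 2 groups compared, WT and Ctr joined, replicate number as a block, regions of the top 10% of sections, a section minimum 2 times as high, and leaving out each of the compared muscles in turn. Mitochondrial genes left out, and thinned sections in the region results, were added after the data had been seen. Lists, region rules, thresholds and the rule for named genes were also fixed before the data were examined.

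On simulated counts with 200 changed genes, the DMD against Ctr comparison recovered 29 of 96 genes changed 2-fold (30.2%) and 84 of 95 changed 4-fold (88.4%), with 4 unchanged genes called. The tendon-region comparison recovered 74 of 100 and 93 of 99, with 9 unchanged genes called. The difference of that effect between groups recovered 43 of 99 and 85 of 100, with 6 unchanged genes called. No pair of muscles held the same library, since every pair differed beyond counting error in at least 36.2% of genes. Spearman correlations across genes between muscles of a group were 0.982 in WT, 0.969 in Ctr and 0.948 to 0.973 in DMD, and that between DMD replicate 3 and Ctr replicate 2 was 0.957 (genes are not independent replicates).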

Results

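RNA was sequenced from serial cryosections of mouse tibialis anterior, the main muscle of the front of the lower leg, in 7 muscles. The labels place 2 muscles in the WT group, 2 in the Ctr group and 3 in the DMD group, DMD being the group named in the series title for Duchenne muscular dystrophy. Column names in the file headers carry hDMD for Ctr, mdx for DMD and pax7 for WT, and the labels do not explain these names. Total counts per muscle were 23560829 and 18389110 in WT, 15698979 and 12391361 in Ctr, and 41699100, 11316565 and 23515625 in DMD. The tables held 525 sections (146 WT, 146 Ctr, 233 DMD), of which 422 were used (114, 116 and 192), with a median of 162467 to 654073 counts per section in the different muscles. The labels do not say that the muscles come from separate animals, so p-values measure the spread between these samples. Intervals and floors given with values cover counting error only.

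Dmd, the dystrophin gene (GRCm38 X:82948870-85206141), was detected in every muscle. Its unscaled level was 13.1 and 8.81 CPM in the WT muscles, 9.98 and 15.3 CPM in the Ctr muscles, and 13.0, 19.8 and 9.70 CPM in the DMD muscles. Group means were 10.9 ± 3.01 CPM (SD, n = 2), 12.7 ± 3.79 CPM (n = 2) and 14.2 ± 5.14 CPM (n = 3). After scaling, the log2 difference of Dmd was -0.18 ± 0.29 for DMD against Ctr (adjusted p = 0.711) and -0.40 ± 0.28 for DMD against WT (adjusted p = 0.359), so Dmd did not pass in either comparison. The human DMD sequence, counted only in the Ctr and DMD tables, gave 22.2 ± 3.78 CPM in Ctr (n = 2) and 18.9 ± 4.14 CPM in DMD (n = 3). Counts of polyA tags over the whole gene do not check whether dystrophin protein or a full-length transcript was made, or which allele a muscle carried.

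Mitochondrially encoded genes took 43.8 ± 3.07% of counts in WT (SD, n = 2), 29.9 ± 0.694% in Ctr (n = 2) and 29.9 ± 4.30% in DMD (n = 3). Between 6.08 and 11.1% of counts lay on the nuclear copies Gm10925, Gm28661 and Gm28437, which share reads with mitochondrial genes. Values of mitochondrial genes, haemoglobin genes and genes overlapping another gene depend on how shared reads were divided, and they are less certain than the others. WT muscles were counted with another annotation than Ctr and DMD muscles, so for differences that involve WT the group and the annotation or batch cannot be told apart.

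DMD was compared with Ctr over whole muscles to ask which genes differ in the dystrophic muscle. The macrophage genes Lgals3, which encodes the lectin galectin-3, and Ctss, which encodes the protease cathepsin S, were 37.2-fold and 28.6-fold higher in DMD. Lgals3 reached 84.2 ± 64.8 CPM in DMD (SD, n = 3) against 2.24 ± 0.404 CPM in Ctr (n = 2), a log2 difference of 5.22 ± 0.92 (adjusted p = 0.0128). Ankrd1, a stress-induced sarcomere protein, rose by 4.80 ± 0.66 (adjusted p = 0.00543), Tnnt2, the embryonic troponin T, by 3.28 ± 0.39 (adjusted p = 0.00392), and Col3a1, a fibrillar collagen, by 3.42 ± 0.53 (adjusted p = 0.00914). Myl3, the slow-fibre myosin light chain, was lower at 8.39 ± 0.467 CPM in DMD (n = 3) against 45.0 ± 5.71 CPM in Ctr (n = 2), a log2 difference of -2.42 ± 0.19 (adjusted p = 0.000905). Cdkn1b, a cell-cycle inhibitor, changed by -2.38 ± 0.30 (adjusted p = 0.00428). The kinase Pdk4, which restrains glucose oxidation, changed by -4.07 ± 0.86 (adjusted p = 0.0212), and the ubiquitin ligase Fbxo32 by -2.55 ± 0.61 (adjusted p = 0.0284). Pdk4 lay at 306 CPM in Ctr replicate 1 and 20.5 in replicate 2, and Fbxo32 had 1183 and 234 CPM.

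By the rule for named genes, the other genes with large changes upward were the macrophage genes Lyz2 and Fcer1g and the collagen Col1a1. Those downward were Acss1, Mcrip2, Ppp1r3c and the gene CT010467.1. In the WT muscles Acss1 lay at 24.4 and 18.0 CPM, CT010467.1 at 150.5 and 106.9 and Fbxo32 at 124 and 160.9. The DMD muscles had 28.4, 25.8 and 33.9 CPM of Acss1, 121, 132 and 84.3 CPM of CT010467.1 and 102, 62.7 and 197 of Fbxo32. None of these genes lay below WT in every DMD muscle, so their falls are against high Ctr values only. Mcrip2, Ppp1r3c and Pdk4 lay below both WT muscles in every DMD muscle. In edgeR, 1740 of 13746 genes passed with Benjamini-Hochberg adjustment, 985 higher and 755 lower in DMD, and 4240 had an unadjusted p under 0.05. The number of called genes was 56 without Ctr replicate 1, 960 without Ctr replicate 2, 583 without DMD replicate 1, 770 without DMD replicate 2 and 3425 without DMD replicate 3. The share that was higher, 56.6%, was 28.6% without Ctr replicate 1 and 46.4% without Ctr replicate 2, so the majority turned. The count was 621 with thinned sections and 683 with only the 2 groups in the fit. Of the 59 named genes that passed, 9 did so without Ctr replicate 1 (Mcrip2, Myl3, Cdkn1b, CT010467.1, Timp1, Hba-a1, Alas2, Comp and Chrna1), and the median adjusted p of the 59 was then 0.150, with no change of sign. Counts of named genes that passed were 33 without Ctr replicate 2, 31 without DMD replicate 1, 32 without DMD replicate 2 and 59 without DMD replicate 3. Without Ctr replicate 1, Lgals3 kept a log2 difference of 5.42 with an adjusted p of 0.126, Pdk4 had -1.08 (adjusted p = 0.338) and Fbxo32 -0.95 (adjusted p = 0.366). Without Ctr replicate 1 the log2 difference was 2.79 for Col3a1, 2.56 for Col1a1, -1.14 for Acss1, -1.82 for Mcrip2 and -1.79 for Ppp1r3c. Without Ctr replicate 2 it was 4.47, 4.46 and -3.48 for the first 3 of these, -4.98 for Pdk4 and -3.29 for Fbxo32. Ankrd1 had 4.01 without DMD replicate 1 and Ppp1r3c -3.23 without DMD replicate 3. Over all alternatives the adjusted p ran from 1.05e-53 to 0.126 for Lgals3, from 1.86e-51 to 0.338 for Pdk4 and from 5.23e-20 to 0.366 for Fbxo32.

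**Figure D1:**
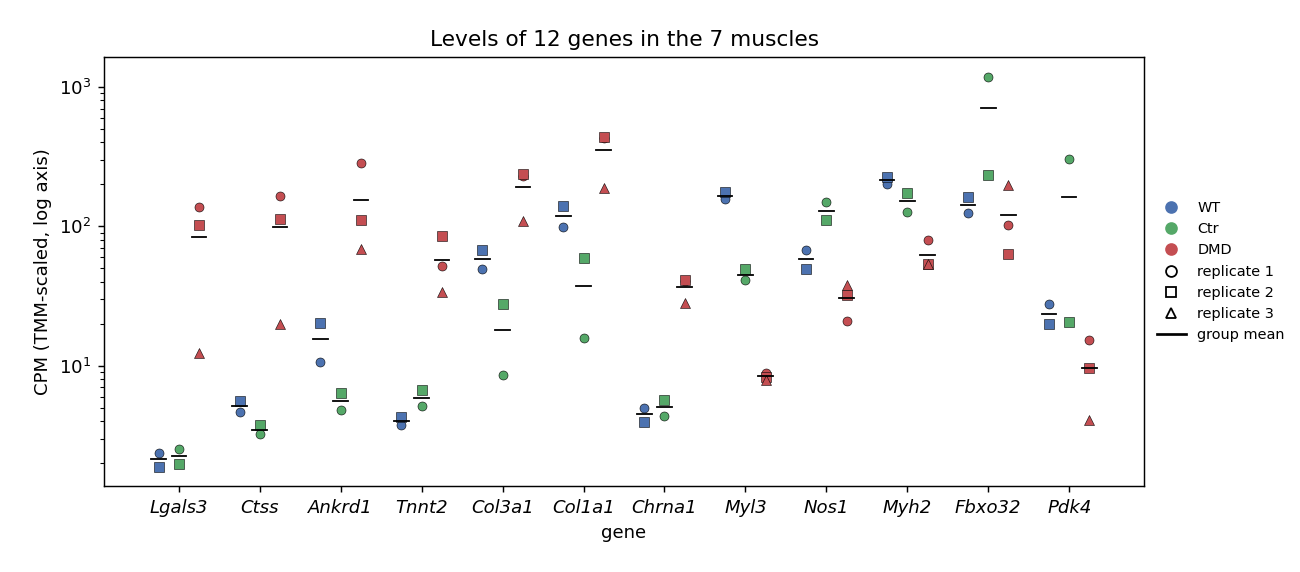
TMM-scaled CPM (log axis) of 12 genes in the 7 muscles, grouped as WT, Ctr and DMD; marker shapes give the replicate and bars the group mean. Lgals3 lay at 84.2 CPM on average in DMD and 2.24 CPM in Ctr, and Myl3 at 8.39 and 45.0 CPM.

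Genes of regenerating fibres were higher in DMD than in Ctr, with 9 of 12 rising and 3 not passing (10 higher when adjusted over the list alone). Mymk, the muscle fusion protein myomaker, had 15.4 ± 9.24 CPM in DMD (SD, n = 3) and 4 counts in all of Ctr. Chrng, the embryonic acetylcholine receptor subunit, was at least 31.9-fold higher against a floor of 3 counts over the Ctr group, and Mymx, the fusion protein myomixer, at least 6.05-fold. The list's median log2 difference was 3.27, or 2.93 with these genes at their bounds (camera adjusted p = 1.48e-06, and adjusted p = 0.363 with an estimated correlation). Among 6 satellite cell genes 1 rose, the stem cell factor Pax7 by 1.77 ± 0.49, and 2 did so adjusted over the list alone (median 0.88, camera adjusted p = 0.0124, and adjusted p = 0.363 with an estimated correlation). Pax7 had only 8 counts in all of Ctr. Its 0.874, 1.27 and 0.915 CPM in the DMD muscles were not above WT, with 1.88 and 1.23 CPM, so this rise is against low Ctr values only. Proliferation genes had 3 of 6 higher, among them the mitotic kinase Cdk1 by 3.49 ± 0.92 and the topoisomerase Top2a by 3.99 ± 1.02, which overlaps Gm23451, and all 6 adjusted over the list alone (median 4.06, camera adjusted p = 0.0105, and adjusted p = 0.58 with an estimated correlation). When Ctr replicate 1 was left out, Mymk had an adjusted p of 0.0838, Pax7 of 0.282 and Cdk1 of 0.265. Pax7, Cdk1 and Top2a also missed the threshold without Ctr replicate 2, DMD replicate 1 or DMD replicate 2, and so did Mymx without Ctr replicate 2 (adjusted p = 0.0804). Mymx (0.198), Chrng (0.0991) and Top2a (0.253) missed it without Ctr replicate 1. With Ctr replicate 1 left out the log2 difference was 5.47 for Mymk and 3.36 for Top2a, and with Ctr replicate 2 left out it was 4.80 for Top2a and 4.13 for Cdk1, while Mymk had 0 CPM in Ctr replicate 1. The DMD muscles had 11.6, 6.94 and 1.05 CPM of Cdk1, against 0.370 and 0.851 CPM in Ctr, so DMD replicate 3 lay close to Ctr. Without DMD replicate 1 the log2 difference was 2.72 for Cdk1 (adjusted p = 0.097) and 3.08 for Top2a (adjusted p = 0.086).

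Macrophage genes rose in 12 of 14 cases (13 adjusted over the list alone). Gpnmb, a lysosomal glycoprotein, rose by 5.37 ± 1.08, and Spp1, the secreted osteopontin, by 6.16 ± 1.45, although Spp1 overlaps Gm42793. The DMD muscles had 138, 102 and 12.4 CPM of Lgals3, 164, 113 and 19.8 CPM of Ctss, 87.8, 40.5 and 5.58 CPM of Gpnmb and 40.5, 12.2 and 1.44 CPM of Spp1, so DMD replicate 3 lay below the other 2. Without DMD replicate 1 Gpnmb was 21.1-fold higher (adjusted p = 0.0353) and Spp1 had a log2 difference of 4.70 (adjusted p = 0.0473). The list's median was 3.02 (camera adjusted p = 1.22e-06, and adjusted p = 0.531 with an estimated correlation). Fibrotic matrix genes rose in 14 of 17 cases (16 adjusted over the list alone), with Timp1, an inhibitor of matrix proteases, by 5.46 ± 0.66 and Postn, the matrix protein periostin, by 4.65 ± 0.79. Their median was 2.66 (camera adjusted p = 2.77e-10, and adjusted p = 0.363 with an estimated correlation). Fibro-adipogenic progenitor genes had 3 of 10 higher (5 adjusted over the list alone), the small proteoglycan Lum by 2.66 ± 0.44, the microfibril gene Mfap5 2.82-fold and the matrix gene Dpt by 1.37 ± 0.33 (median 0.76, camera adjusted p = 0.00857, and adjusted p = 0.58 with an estimated correlation). Of the 8 interferon response genes none passed over all genes and 2 were higher adjusted over the list alone (median 1.45, camera adjusted p = 0.0956). The 2 measured lymphocyte genes (median 1.78, camera adjusted p = 0.193) and the 2 granulocyte genes (median -1.44, camera adjusted p = 0.207) did not pass. Without Ctr replicate 1, Gpnmb (adjusted p = 0.143), Spp1 (0.205), Postn (0.122), Lum (0.121), Mfap5 (0.242) and Dpt (0.241) missed the threshold, and Timp1 passed (0.0203). The log2 difference was then 6.21 for Gpnmb and 3.84 for Postn, while Timp1 had 0 CPM in Ctr replicate 2, and without Ctr replicate 2 it was 4.65 for Timp1 and 5.96 for Postn. Gpnmb, Spp1 and Mfap5 also missed the threshold without Ctr replicate 2, and Mfap5 and Dpt without DMD replicate 1 or DMD replicate 2.

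Tendon genes, which also define the tendon-marker-rich sections, rose in 5 of 7 cases (7 adjusted over the list alone), with the cartilage matrix protein Comp by 3.95 ± 0.43, the tendon membrane protein Tnmd by 3.60 ± 0.69 and Cilp2 by 1.90 ± 0.49. Their median was 1.90 (camera adjusted p = 7.64e-05, and adjusted p = 0.363 with an estimated correlation). Myotendinous junction genes rose in 3 of 4 cases (3 adjusted over the list alone), with the collagens Col24a1 by 2.93 ± 0.73 and Col22a1 by 1.57 ± 0.45 and the thrombospondin Thbs4 by 1.22 ± 0.32 (median 1.39, camera adjusted p = 0.0129, and adjusted p = 0.363 with an estimated correlation). Bone, cartilage and skin genes, 3 of them measured, did not pass (median 0.58, camera adjusted p = 0.65). Of these genes, Comp passed without Ctr replicate 1 (adjusted p = 0.042) and Tnmd (0.122), Cilp2 (0.267), Col24a1 (0.173), Col22a1 (0.338) and Thbs4 (0.267) did not. The log2 difference was then 2.54 for Tnmd, 1.18 for Cilp2 and 3.93 for Col24a1, and without Ctr replicate 2 it was 2.95 for Cilp2 and 2.20 for Col22a1. Tnmd lay at 0.0616 CPM in Ctr replicate 1 and 0.851 CPM in replicate 2. All of Ctr held 6 counts of Comp, 11 of Tnmd, 14 of Cilp2 and 5 of Col24a1, so the folds of these genes rest on few Ctr counts. With WT and Ctr joined, Tnmd, Cilp2, Col22a1 and Thbs4 missed the threshold, and Cilp2 had a log2 difference of -0.067. Cilp2, Col22a1 and Thbs4 also missed it without DMD replicate 1 or DMD replicate 2, Col24a1 without DMD replicate 2, and Col22a1, Col24a1 and Thbs4 without Ctr replicate 2.

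Of the synaptic genes that were not used to define sections, 4 of 10 rose (4 adjusted over the list alone). Chrna1, the acetylcholine receptor alpha subunit, had 36.7 ± 7.49 CPM in DMD (SD, n = 3) against 5.01 ± 0.980 CPM in Ctr (n = 2), a log2 difference of 2.88 ± 0.27 (adjusted p = 0.00186). Chrnb1, the beta subunit, rose by 1.67 ± 0.24 and the esterase Ache by 1.60 ± 0.37. The list's median was 1.04 (camera adjusted p = 0.00857, and adjusted p = 0.363 with an estimated correlation). Of the 6 synaptic genes that define sections 2 rose, Chrne by 1.17 ± 0.34 and Colq by 1.98 ± 0.49, which overlaps Gm49387, and all 6 adjusted over the list alone (median 1.49, camera adjusted p = 0.00281, and adjusted p = 0.363 with an estimated correlation). Among 7 Schwann cell genes Pmp22, a membrane protein, was higher by 0.86 ± 0.21. The list's median was -0.69 (camera adjusted p = 0.0299, and adjusted p = 0.363 with an estimated correlation). Chrna1 passed without Ctr replicate 1 (adjusted p = 0.0306), while Chrnb1 (0.0943), Ache (0.152), Chrne (0.325), Colq (0.251) and Pmp22 (0.227) did not. Ache was then 1.99-fold higher, and without Ctr replicate 2 the log2 difference was 2.55 for Ache and 1.83 for Chrne. Pmp22 also missed the threshold without Ctr replicate 2, DMD replicate 1 or DMD replicate 2. Ache and Chrne missed it without DMD replicate 1 or DMD replicate 2, and Colq without Ctr replicate 2 or DMD replicate 1.

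Among fast fibre genes 1 of 12 was lower (1 adjusted over the list alone), the type 2A myosin Myh2 by a log2 difference of -1.27 ± 0.24 (list median -0.41, camera adjusted p = 0.0346, and adjusted p = 0.587 with an estimated correlation). Slow fibre genes had Myl3 lower and the calcium pump Atp2a2 higher by 1.08 ± 0.28 among 10 (1 and 1 adjusted over the list alone), with a median of 0.39, a mean of -0.20 and a camera adjusted p of 0.83 in the downward direction of the mean. Oxidative phosphorylation genes had 2 of 16 lower, Cox4i1 by -0.94 ± 0.22 and Uqcrc1 by -0.84 ± 0.21, both parts of the respiratory chain, and 3 adjusted over the list alone (median -0.38, camera adjusted p = 0.00134, and adjusted p = 0.58 with an estimated correlation). Of 9 mitochondrially encoded genes mt-Nd5 was lower by -1.08 ± 0.31, and none adjusted over the list alone (median -0.09, camera adjusted p = 0.335). The 12 glycolysis genes did not pass (median -0.16, camera adjusted p = 0.17). In the dystrophin complex 1 of 11 genes was lower (1 adjusted over the list alone): Nos1, the neuronal nitric oxide synthase, had 30.5 ± 8.70 CPM in DMD (SD, n = 3) against 130 ± 27.3 CPM in Ctr (n = 2), a log2 difference of -2.09 ± 0.28 (adjusted p = 0.0048). That list had a median of 0.05, a mean of -0.08 and a camera adjusted p of 0.764 in the downward direction. Without Ctr replicate 1, Nos1 (adjusted p = 0.0545), Myh2 (0.0773), Atp2a2 (0.283), Cox4i1 (0.171), Uqcrc1 (0.185) and mt-Nd5 (0.142) missed the threshold. Without Ctr replicate 2 the same was true of Myh2, Atp2a2, Cox4i1, Uqcrc1 and mt-Nd5, without DMD replicate 1 of Atp2a2, Cox4i1, Uqcrc1 and mt-Nd5, and without DMD replicate 2 of Atp2a2, Uqcrc1 and mt-Nd5.

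Erythroid genes had 2 of 5 lower in DMD (5 adjusted over the list alone), with the alpha globin Hba-a1 at 1906 ± 631 CPM in DMD (SD, n = 3) against 7130 ± 5606 CPM in Ctr (n = 2) and the haem synthesis gene Alas2 changed by -1.57 ± 0.39. Their median was -1.57 (camera adjusted p = 0.00867, and adjusted p = 0.58 with an estimated correlation). Without Ctr replicate 2, Hba-a1 had a log2 difference of -0.74 (adjusted p = 0.261) and Alas2 of -0.67 (adjusted p = 0.263), and without Ctr replicate 1 Hba-a1 had -2.54. Hba-a1 and Alas2 also missed the threshold without DMD replicate 1 or DMD replicate 2, and with WT and Ctr joined. Of 7 pericyte and smooth muscle genes 2 were lower (1 higher and 2 lower adjusted over the list alone), the contractile genes Tagln by -1.92 ± 0.29 and Myh11 by -0.83 ± 0.21 (median -0.36, camera adjusted p = 0.194). Endothelial genes, 8 in number, did not pass (median -0.12, camera adjusted p = 0.291), nor did 5 adipocyte genes (median -0.29, camera adjusted p = 0.206). Atrophy and denervation genes went both ways among 5, with the transcription factor Runx1 higher by 3.28 ± 0.56 and the ubiquitin ligases Fbxo32 and Trim63 lower (1 and 2 adjusted over the list alone, median -1.57, camera adjusted p = 0.506). Of 8 immediate early and heat shock genes Atf3, a stress-induced transcription factor, rose by 1.68 ± 0.48 (1 adjusted over the list alone, median 0.35, camera adjusted p = 0.651). When Ctr replicate 1 was left out, Tagln (adjusted p = 0.0897), Myh11 (0.126), Runx1 (0.0852), Trim63 (0.642), Fbxo32 (0.366) and Atf3 (0.157) missed the threshold. The log2 difference was then -0.30 for Trim63, -0.95 for Fbxo32, 3.99 for Runx1 and 2.34 for Atf3, and without Ctr replicate 2 it was -2.95 for Trim63 and -3.29 for Fbxo32. Myh11 and Atf3 also missed the threshold without Ctr replicate 2, and Myh11, Trim63, Fbxo32 and Atf3 without DMD replicate 1 or DMD replicate 2.

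With the preset correlation, camera called 14 of 27 lists for DMD against Ctr, 10 upward and 4 downward. With an estimated correlation it called 0 of them, while fry called 8 as moving on balance in 1 direction and 16 as changed in either direction. When a muscle is left out of a group of 2, the lone muscle is assumed to vary like the other groups.

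**Figure D2:**
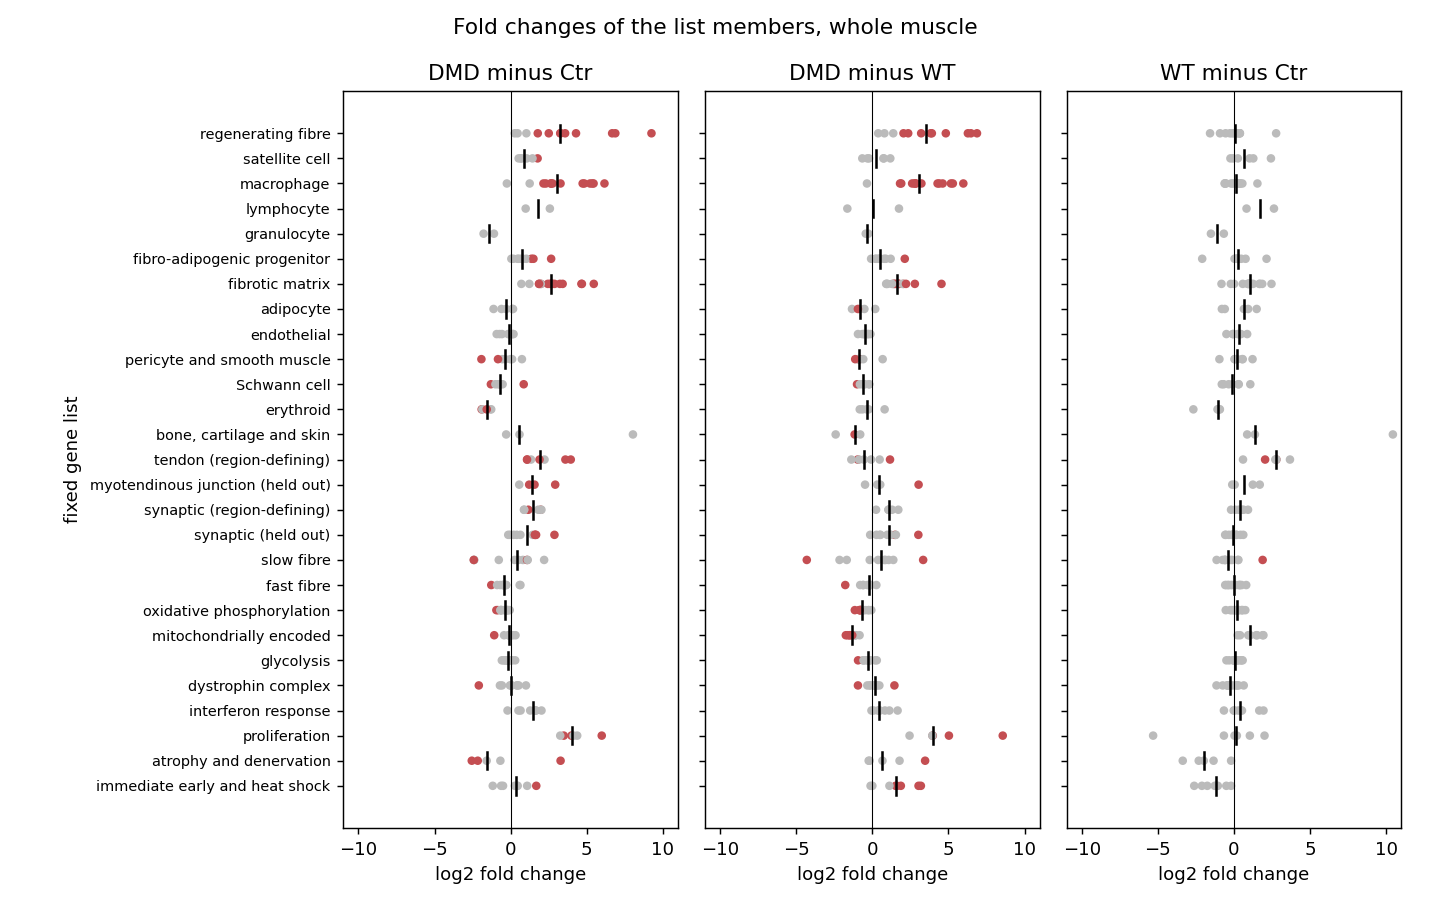
Log2 fold change of each measured member of the fixed gene lists in the 3 whole-muscle comparisons; red points passed at an adjusted p below 0.05 and ticks mark list medians. The fibrotic matrix median was 2.66 for DMD against Ctr and 1.65 for DMD against WT.

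DMD was also compared with WT, the second group of muscles without the DMD label. Lgals3 was 39.2-fold higher in DMD, at 84.2 ± 64.8 CPM (SD, n = 3) against 2.13 ± 0.344 CPM in WT (n = 2), and Tnnt2 rose by 3.83 ± 0.41 (adjusted p = 0.00179). Myl3 was lower at 8.39 CPM against 166 ± 13.7 CPM in WT (n = 2), a log2 difference of -4.30 ± 0.20 (adjusted p = 1.69e-05). Mb, the oxygen carrier myoglobin, changed by -2.18 ± 0.25 (adjusted p = 0.00242) and Csrp3, a Z-disc protein, by -2.12 ± 0.43 (adjusted p = 0.0162). Other genes with large changes upward were Ctss, Ankrd1, Tmsb10, C1qb, Cd44 and Fcer1g. Those downward were Cmbl, Myoz2, Ankrd2 and the mitochondrial tRNA genes mt-Tg and mt-Ti, the latter overlapping mt-Nd1. In edgeR 2085 genes passed, 1134 higher and 951 lower, with 4563 at an unadjusted p under 0.05. The count was 78 without WT replicate 1, 68 without WT replicate 2, 893 without DMD replicate 1, 1082 without DMD replicate 2 and 3595 without DMD replicate 3. The share that was higher, 54.4%, was 15.4% without WT replicate 1, 20.6% without WT replicate 2 and 49.8% without DMD replicate 1, so the majority turned, and the count was 543 with thinned sections. Of the 54 named genes that passed, 9 did so without WT replicate 1 (Tnnt2, Myl3, Cmbl, mt-Ti, Myoz2, Mb, Csrp3, Ankrd2 and Chrna1) and 8 without WT replicate 2, where Csrp3 had a log2 difference of -1.15 and an adjusted p of 0.185. Lgals3 then had an adjusted p of 0.11 without WT replicate 1 and 0.134 without WT replicate 2 (7.25e-56 to 0.134 over all alternatives). Without DMD replicate 1 the log2 difference was 4.70 for Lgals3, 3.68 for Ctss, 2.52 for Ankrd1 and -3.70 for mt-Tg. Counts of named genes that passed were 36 without DMD replicate 1, 31 without DMD replicate 2 and 53 without DMD replicate 3.

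Against WT, 9 of 12 regenerating fibre genes rose (9 adjusted over the list alone). Mymx was at least 6.66-fold higher and Mymk higher by 6.28 ± 0.92 (median 3.52, or 2.97 with genes at their bounds, camera adjusted p = 3.27e-06, and adjusted p = 0.433 with an estimated correlation). Macrophage genes rose in 13 of 14 cases (13 adjusted over the list alone, median 3.05, camera adjusted p = 4.63e-06, and adjusted p = 0.435 with an estimated correlation). Fibrotic matrix genes rose in 10 of 17 (15 adjusted over the list alone). Timp1 rose by 4.55 ± 0.59 and Postn by 2.80 ± 0.66 (median 1.65, camera adjusted p = 7.61e-06, and adjusted p = 0.435 with an estimated correlation). Proliferation genes rose in 3 of 6 (6 adjusted over the list alone), Cenpf, a kinetochore protein, at least 20.8-fold (at least 8.44-fold without DMD replicate 1, with 4.44, 1.47 and 0.174 CPM in the 3 DMD muscles; list camera adjusted p = 0.0182, and adjusted p = 0.563 with an estimated correlation). Immediate early and heat shock genes rose in 5 of 8 (6 adjusted over the list alone). The transcription factors Fos and Junb were among them, Fos by 3.19 ± 0.66 and Junb by 3.04 ± 0.66 (median 1.58, camera adjusted p = 0.00492, and adjusted p = 0.433 with an estimated correlation). Synaptic genes not used to define sections rose in 2 of 10 (3 adjusted over the list alone), Chrna1 by 3.02 ± 0.28 and Chrnb1 2.82-fold (median 1.08, camera adjusted p = 0.00413, and adjusted p = 0.433 with an estimated correlation). Those that define sections reached a median of 1.08, with 5 of 6 higher only when adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.433 with an estimated correlation). Without WT replicate 2, Mymk (adjusted p = 0.0883), Postn (0.134), Cenpf (0.197), Fos (0.165), Junb (0.168) and Chrnb1 (0.127) missed the threshold, and Timp1 did so without WT replicate 1 (0.0688). Mymx missed it without either WT muscle (0.172 and 0.164). Without WT replicate 1 the first 6 genes missed it as well, and Postn also without DMD replicate 1 or DMD replicate 2. Without WT replicate 1 the log2 difference was 7.45 for Mymk and 3.90 for Timp1, and without WT replicate 2 it was 5.32 for Timp1 and 3.54 for Postn.

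Oxidative phosphorylation genes were lower than in WT in 7 of 16 cases (12 adjusted over the list alone), with Sdhb, a subunit of complex II, changed by -1.15 ± 0.20 (median -0.70, camera adjusted p = 7.61e-06, and adjusted p = 0.433 with an estimated correlation). Mitochondrially encoded genes were lower in 5 of 9 (9 adjusted over the list alone), mt-Atp6 by -1.74 ± 0.30, which overlaps mt-Atp8 and mt-Co3, and mt-Nd4 by -1.49 ± 0.32, which overlaps mt-Nd4l (median -1.32, camera adjusted p = 7.61e-06, and adjusted p = 0.433 with an estimated correlation). Fast fibre genes had Myh2 lower by -1.78 ± 0.24 among 12 (camera adjusted p = 0.0231, and adjusted p = 0.563 with an estimated correlation). Glycolysis genes had Gapdh lower by -0.94 ± 0.24 among 12 (camera adjusted p = 0.0355, and adjusted p = 0.68 with an estimated correlation). Pericyte and smooth muscle genes were lower in 3 of 7, with Rgs5, a regulator of G-protein signals, by -0.89 ± 0.19, and 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.433 with an estimated correlation). The 8 endothelial genes had a median of -0.47 (camera adjusted p = 0.033, and adjusted p = 0.433 with an estimated correlation). The 7 Schwann cell genes had a median of -0.58 (camera adjusted p = 0.0214, and adjusted p = 0.433 with an estimated correlation). Bone, cartilage and skin genes had Alpl lower by -1.16 ± 0.30 among 3 (camera adjusted p = 0.0367, and adjusted p = 0.433 with an estimated correlation). Tendon genes moved apart, Comp higher by 1.16 ± 0.31 and Fmod, a proteoglycan, lower by -0.96 ± 0.28 (median -0.56, camera adjusted p = 0.552). Nos1 was lower by -0.94 ± 0.28 and the syntrophin Sntb1 higher by 1.45 ± 0.36 among 11 dystrophin complex genes (camera adjusted p = 0.786). Slow fibre genes had a median of 0.58 and a mean of -0.05 (camera adjusted p = 0.949). Without WT replicate 2, every gene named in this paragraph missed the threshold, for example Sdhb (adjusted p = 0.127), mt-Atp6 (0.13), Myh2 (0.0733), Rgs5 (0.197) and Fmod (0.371), and the same held without WT replicate 1, with adjusted p = 0.0503 for Myh2. Gapdh, Alpl, Comp, Fmod, Nos1 and Sntb1 also missed it without DMD replicate 1 or DMD replicate 2 (Fmod with 0.121 without DMD replicate 1). Fmod did so without DMD replicate 3 (0.0528) and mt-Nd4 without DMD replicate 2 (0.051).

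Lists that did not pass camera against WT were satellite cell (median 0.26), lymphocyte (0.06), granulocyte (-0.35), fibro-adipogenic progenitor (0.50), adipocyte (-0.82), erythroid (-0.37), myotendinous junction (0.43), interferon response (0.47) and atrophy and denervation genes (0.67). Camera leaned downward for the satellite cell and lymphocyte genes in spite of their positive medians. In these lists Pi16, a marker of progenitors in connective tissue, rose by 2.13 ± 0.61, Fabp4, a fatty acid carrier, changed by -0.94 ± 0.22, Col24a1 rose by 3.04 ± 0.73 and Runx1 rose by 3.47 ± 0.56. Camera called 15 of 27 lists, 7 upward and 8 downward, 0 with an estimated correlation, and fry called 8. Without WT replicate 2, Pi16 (adjusted p = 0.254), Fabp4 (0.269), Col24a1 (0.184) and Runx1 (0.116) missed the threshold, as they did without WT replicate 1. Runx1 had a log2 difference of 2.86 without DMD replicate 1. Pi16 also missed the threshold without DMD replicate 2 (log2 difference 1.30, adjusted p = 0.0728), Fabp4 without DMD replicate 1 (0.0578) or DMD replicate 2 (0.0641), and Col24a1 without DMD replicate 2 (0.0502).

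The WT and Ctr muscles were compared with each other as the background between groups without the DMD label. Myl3 had 166 ± 13.7 CPM in WT (SD, n = 2) against 45.0 ± 5.71 CPM in Ctr (n = 2), a log2 difference of 1.88 ± 0.21 (adjusted p = 0.0115). Nmrk2, a kinase of NAD synthesis, was higher by 2.54 ± 0.43 (adjusted p = 0.0479) and Actn2, a Z-disc crosslinker, by 1.59 ± 0.23 (adjusted p = 0.0464), and Fzd4, a Wnt receptor, was lower by -1.76 ± 0.30 (adjusted p = 0.0479). Other genes with large changes were mt-Tw (which overlaps mt-Nd2), 2210016F16Rik, Gm13341 and Uqcrb upward and Srrm2, Mical2, Atp6v0a1 and Gatad2b downward. In edgeR 50 of 13746 genes passed, 23 higher and 27 lower in WT, and 2481 had an unadjusted p under 0.05. The count was 2 without WT replicate 1, 2 without WT replicate 2, 3 without Ctr replicate 1 and 97 without Ctr replicate 2. It was 586 with only the 2 groups in the fit and 475 with the DESeq2 Wald test. The share higher in WT, 46.0%, was 60.3% of 63 genes with thinned sections and 27.8% without Ctr replicate 2. The few genes called without another muscle were 100% higher without WT replicate 1 or 2 and 66.7% without Ctr replicate 1. Nmrk2 had a log2 difference of 1.95 without Ctr replicate 1 and 3.46 without Ctr replicate 2. Of 14 named genes that passed, 0 did so in edgeR without WT replicate 1, WT replicate 2 or Ctr replicate 1, with median adjusted p of 0.228, 0.493 and 0.206, and 4 without Ctr replicate 2. Genes with exons overlapped on the same strand by a gene outside the set shared by the 2 annotations were 4 of the 50 called (8%). They were 241 of the 13746 tested (1.75%; Fisher's exact test, two-sided p = 0.0113), so the calls held more genes exposed to the difference of annotation.

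Tendon genes were the list furthest apart between WT and Ctr, with 2 of 7 higher in WT (6 adjusted over the list alone), Comp by 2.79 ± 0.48 and Fmod by 2.05 ± 0.34 (median 2.77, camera adjusted p = 3.74e-07, and adjusted p = 0.559 with an estimated correlation). Fibrotic matrix genes had a median of 1.06 with none past the threshold (camera adjusted p = 0.000263, and adjusted p = 0.778 with an estimated correlation). Mitochondrially encoded genes had a median of 1.04 and 4 of 9 higher adjusted over the list alone (camera adjusted p = 4.92e-05, and adjusted p = 0.666 with an estimated correlation). Bone, cartilage and skin genes had a median of 1.38 and all 3 higher adjusted over the list alone (camera adjusted p = 0.00842, and adjusted p = 0.559 with an estimated correlation). Satellite cell genes had a median of 0.64 and 3 of 6 higher adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.559 with an estimated correlation). Immediate early and heat shock genes had a median of -1.21 with 5 of 8 lower adjusted over the list alone (camera adjusted p = 0.00105, and adjusted p = 0.562 with an estimated correlation). Erythroid genes had a median of -1.04 with 1 of 5 lower adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.819 with an estimated correlation). Camera called 7 of 27 lists, 5 upward and 2 downward, 0 with an estimated correlation, and fry called 0. Comp and Fmod missed the threshold without WT replicate 1, WT replicate 2 (adjusted p of 0.469 for Comp and 0.493 for Fmod) or Ctr replicate 1, and Comp also without Ctr replicate 2.

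Tendon-marker-rich sections were compared with the remaining sections to ask what marks the muscle end. Thinned to 30384 counts, Ctr sections averaged 0.213 and 0.273 counts of the defining genes, against 1.26 to 1.88 in WT and DMD. So tendon-region results that use Ctr rest on few marker counts. Mss51, a mitochondrial protein of fast fibres, had 57.5 ± 20.3 CPM in tendon-marker-rich sections (SD, n = 7) against 27.4 ± 6.84 CPM in the remaining sections (n = 7), a log2 difference of 1.13 ± 0.08 (adjusted p = 3.41e-11), and it was higher in 7 of 7 muscles. Thbs4, a held-out myotendinous gene, rose by 0.53 ± 0.07 (adjusted p = 2.04e-05), the collagen Col1a2 by 0.51 ± 0.08 (adjusted p = 9.42e-05) and Cbr2, a carbonyl reductase, by 0.40 ± 0.06 (adjusted p = 4.85e-05). Actc1, cardiac actin, changed by -1.20 ± 0.08 (adjusted p = 4.82e-12), Mbp, a myelin protein, by -1.34 ± 0.15 (adjusted p = 9.57e-07) and Myh2 by -0.66 ± 0.09 (adjusted p = 1.42e-05). Other named rises were those of Prelp, Odc1, Pmepa1 and Smyd2, and other falls those of Pi16, Ldhb, Csrp3, Ankrd2 and Lrtm1. In edgeR 187 of 11767 genes passed besides the defining genes, 49 higher and 138 lower, and 1325 had an unadjusted p under 0.05. The share that was higher, 26.2% of these genes, was 42.5% of 160 genes with DESeq2 size factors. With each section thinned to 1 total the count was 52, and with the top 10% of sections it was 86. The median total of the tendon-marker-rich sections was below that of the remaining sections in the WT and DMD muscles (for example 218114 against 481319 in WT replicate 1 and 416243 against 729194 in DMD replicate 1) and above it in the Ctr muscles (247009 against 235608 and 230405 against 205314). The count was 103 and 99 without WT replicate 1 and 2, 68 and 83 without Ctr replicate 1 and 2, and between 141 and 182 without a DMD muscle. Of the 41 named genes that passed, 28 did so without WT replicate 1, 29 without WT replicate 2, 25 without Ctr replicate 1 and 25 without Ctr replicate 2. The corresponding counts were 35, 37 and 41 without DMD replicate 1, 2 and 3. Prelp missed the threshold without WT replicate 1 (adjusted p = 0.122) and Ctr replicate 1, Odc1 without WT replicate 2 (0.0979) and Ctr replicate 2, and Pmepa1 without any 1 of the WT or Ctr muscles or DMD replicate 1 (at most 0.38).

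The tendon genes that define these sections had a median of 2.03, which follows from the choice of sections. The held-out myotendinous genes rose in 2 of 4 (3 adjusted over the list alone), with Col22a1 by 1.76 ± 0.31 (median 0.87, camera adjusted p = 0.000218, and adjusted p = 0.0429 with an estimated correlation). Fibrotic matrix genes rose in 3 of 17 (3 adjusted over the list alone), Col1a1 by 0.72 ± 0.11 (camera adjusted p = 0.00611, and adjusted p = 0.238 with an estimated correlation). The 4 Schwann cell genes had a median of -1.08 (camera adjusted p = 2.37e-06, and adjusted p = 0.0322 with an estimated correlation). Erythroid genes were lower in 4 of 5 (5 adjusted over the list alone), Hbb-bt, a beta globin, by -0.82 ± 0.11 (camera adjusted p = 4.6e-05, and adjusted p = 0.223 with an estimated correlation). The fall of Hbb-bt came from WT (-1.26 and -1.16) and Ctr (-0.95 and -1.78), while the DMD muscles had 0.075, -0.39 and 0.59, and Hba-a1 had 0.23, -0.34 and 0.72 there. Endothelial genes were lower in 3 of 8 (3 adjusted over the list alone), Kdr by -0.30 ± 0.05 (camera adjusted p = 0.00141, and adjusted p = 0.0988 with an estimated correlation). Pericyte and smooth muscle genes were lower in 2 of 7 (3 adjusted over the list alone), Acta2 by -0.52 ± 0.06 (camera adjusted p = 0.00144, and adjusted p = 0.143 with an estimated correlation). Col22a1 had 0.96, 0.86 and -0.31 in the DMD muscles. It missed the threshold without WT replicate 1 (adjusted p = 0.109) or Ctr replicate 2, and Col1a1 without Ctr replicate 2 (0.128).

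Oxidative phosphorylation genes were lower in the tendon-marker-rich sections in 4 of 16 cases (15 adjusted over the list alone, median -0.18, camera adjusted p = 2.37e-06, and adjusted p = 0.203 with an estimated correlation). Mitochondrially encoded genes were lower in 3 of 9 (9 adjusted over the list alone, median -0.20, camera adjusted p = 0.00125, and adjusted p = 0.363 with an estimated correlation). Slow fibre genes were lower in 2 of 8 (2 adjusted over the list alone), Casq2, a calcium store protein, by -0.65 ± 0.12 (camera adjusted p = 0.0189, and adjusted p = 0.339 with an estimated correlation). Fast fibre genes had 1 of 12 higher and 2 lower (6 and 2 adjusted over the list alone), with a median of 0.09 and a mean of -0.00 and camera leaning upward (camera adjusted p = 0.0189, and adjusted p = 0.242 with an estimated correlation). Glycolysis genes had a median of 0.04 with none past the threshold (camera adjusted p = 0.0395, and adjusted p = 0.363 with an estimated correlation). Among held-out synaptic genes Prkar1a, a kinase subunit, was lower by -0.50 ± 0.07 and Chrna1 by -1.27 ± 0.30 (median -0.29, camera adjusted p = 0.087). Regenerating fibre genes had a median of 0.09 and a mean of -0.21 with Actc1 lower (camera adjusted p = 0.98). Macrophage genes had a median of -0.04 with none past the threshold (camera adjusted p = 0.691). Casq2 missed the threshold without Ctr replicate 1 (adjusted p = 0.0868) and Chrna1 without WT replicate 1 (0.366) or Ctr replicate 1, while it had a log2 difference of -3.40 without WT replicate 2. In single muscles Chrna1 had -4.24 and -0.44 in WT, -2.62 and -1.02 in Ctr, and -0.056, 0.31 and -0.15 in DMD, so its average fall came from WT and Ctr. Casq2 had -0.25, -0.25 and 0.075 in the DMD muscles. Camera called 11 of the 23 lists that do not define regions, 4 upward and 7 downward. With an estimated correlation it called 2, the Schwann cell and myotendinous junction genes.

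Sections rich in synaptic markers were compared with the remaining sections to ask what marks the zone of nerve contact. Besides the 6 defining genes, whose rise follows from the choice of sections (median 1.65), 1 gene passed in edgeR: Mss51 was lower at 19.5 ± 6.25 CPM (SD, n = 7) against 27.4 ± 6.84 CPM (n = 7). Its log2 difference was -0.49 ± 0.10 (adjusted p = 0.0247), and it was lower in 7 of 7 muscles. Prkar1a was higher by 0.28 ± 0.06 in 7 of 7 muscles and did not pass (adjusted p = 0.0553). The held-out synaptic genes had a median of 0.25 with 2 of 8 higher adjusted over the list alone (camera adjusted p = 0.000546, and adjusted p = 0.0609 with an estimated correlation). Schwann cell genes had a median of 0.30 with 2 of 4 higher adjusted over the list alone (camera adjusted p = 0.000546, and adjusted p = 0.0861 with an estimated correlation). Macrophage genes had a median of 0.20 (camera adjusted p = 0.00503, and adjusted p = 0.253 with an estimated correlation). Erythroid genes had a median of -0.29 with 5 of 5 lower adjusted over the list alone, mitochondrially encoded genes a median of -0.11 (both camera adjusted p = 0.0142, and adjusted p = 0.624 with an estimated correlation). Myotendinous junction genes had a median of -0.56 (camera adjusted p = 0.0336, and adjusted p = 0.253 with an estimated correlation). Camera called 6 of the 23 lists that do not define regions, 3 upward and 3 downward, and 0 with an estimated correlation. At an unadjusted p under 0.05 there were 631 genes. Mss51 missed the threshold without WT replicate 2 (adjusted p = 0.355), Ctr replicate 1 (0.211), Ctr replicate 2 (0.62) or DMD replicate 3 (0.0977; 0.013 to 0.971 over all alternatives), where 0 genes were called in edgeR each time, and 2 genes were called without DMD replicate 2. The calls turned upward under some alternatives: with a mean of at least 20 CPM 1 gene passed and with the top 10% of sections 3 passed, all higher, and Mss51 was not among them (adjusted p = 0.108 and 0.637).

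The tendon-region effect was then compared between DMD and Ctr to ask whether the muscle end differs in the dystrophic muscle. The rise of Mss51 was smaller in DMD, with 0.15, 0.71 and 0.38 in the DMD muscles against 1.64 and 1.59 in the Ctr muscles, and 1.33 and 1.41 in the WT muscles (log2, tendon-marker-rich minus remaining). The difference of the effects was -1.27 ± 0.19 (edgeR adjusted p = 0.00158). Hbb-bt fell at the tendon-marker-rich sections of the Ctr muscles by a log2 difference of -0.95 and -1.78 but had 0.075, -0.39 and 0.59 in the DMD muscles, a difference of 1.53 ± 0.25 (edgeR adjusted p = 0.00556). These were the 2 genes called of 11767, with 617 at an unadjusted p under 0.05. Mss51 missed the threshold without Ctr replicate 1 (-1.23, adjusted p = 0.204) or Ctr replicate 2 (-1.31, adjusted p = 0.0577), and Hbb-bt without Ctr replicate 2 (1.06, adjusted p = 1) or DMD replicate 3 (1.27, adjusted p = 0.169). Over all alternatives the adjusted p ran from 1.79e-05 to 0.997 for Mss51 and from 1.79e-05 to 1 for Hbb-bt. The number of called genes was 5 without Ctr replicate 1, 0 in edgeR without Ctr replicate 2, and 4, 10 and 1 without DMD replicate 1, 2 and 3. Erythroid genes had a median of 1.44, with 1 of 5 past the threshold and 5 adjusted over the list alone (camera adjusted p = 1.43e-06, and adjusted p = 0.449 with an estimated correlation). Satellite cell genes had a median of 0.70 (camera adjusted p = 0.00588, and adjusted p = 0.178 with an estimated correlation).

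For the synaptic-region effect, 0 genes differed between DMD and Ctr in edgeR, with 540 at an unadjusted p under 0.05 and 0 without any 1 of the Ctr or DMD muscles (leaving out a WT muscle was not run). Camera called 0 of the 23 lists that do not define regions for this difference, and for the tendon-region effect it called only the erythroid and satellite cell lists among them.

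**Figure D3:**
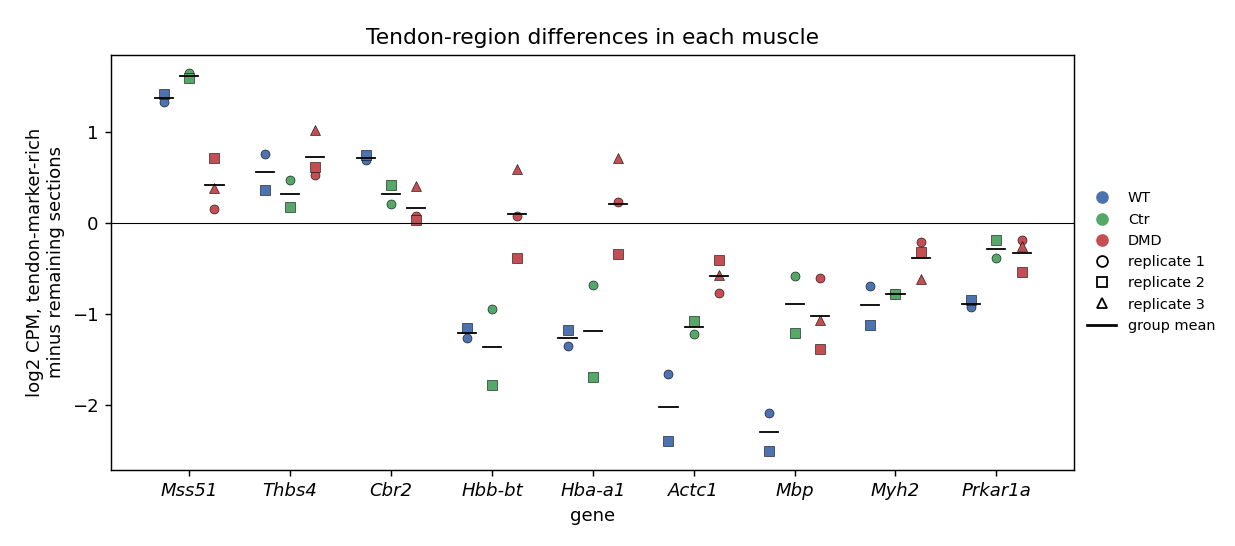
Log2 CPM in tendon-marker-rich minus remaining sections of each muscle (1 point per muscle, coloured by group) for 9 genes. Mss51 lay between 1.33 and 1.64 in the WT and Ctr muscles and between 0.15 and 0.71 in the DMD muscles.

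DMD was compared with Ctr inside each kind of section to ask whether the whole-muscle differences appear in all of them. In tendon-marker-rich sections Gpnmb was higher by 5.73 ± 1.19, Ctss by 5.10 ± 0.86 and Tnnt2 by 4.03 ± 0.52, and Chrna1 rose from 1.36 ± 1.02 CPM in Ctr (SD, n = 2) to 39.5 ± 13.0 CPM in DMD (n = 3), a log2 difference of 4.91 ± 0.62 (adjusted p = 0.00754). In synaptic-marker-rich sections Ankrd1 was higher by 6.04 ± 0.79, Lgals3 by 5.48 ± 0.95 and Col3a1 by 3.89 ± 0.52, with Myl3 changed by -2.58 ± 0.29 and Ankrd2 by -2.44 ± 0.28, and Chrna1 rose by 2.21 ± 0.37. In the remaining sections Lgals3 was higher by 5.47 ± 0.94 and Chrna1 by 2.88 ± 0.27, while Myl3 changed by -2.38 ± 0.21 and Cdkn1b by -2.45 ± 0.28. In edgeR 560 of 8600 genes passed in tendon-marker-rich sections (314 higher, 246 lower, 2163 at an unadjusted p under 0.05), 831 of 10256 in synaptic-marker-rich sections (483 and 348, 2602 unadjusted) and 1347 of 12825 in the remaining sections (739 and 608, 3669 unadjusted). Without Ctr replicate 1 these counts were 30, 45 and 52, and without Ctr replicate 2 they were 373, 411 and 749. Most called genes were then lower, with 40.0, 33.3 and 23.1% higher without Ctr replicate 1 and 46.1, 46.7 and 45.0% without Ctr replicate 2. Without DMD replicate 1 they were 157, 390 and 470, without DMD replicate 2 they were 132, 516 and 640, and without DMD replicate 3 they were 1364, 1683 and 2730. Of the named genes, 6 of 33, 8 of 40 and 8 of 60 passed without Ctr replicate 1, with median adjusted p of 0.145, 0.148 and 0.143.

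Fibrotic matrix genes rose in 11 of 16, 14 of 17 and 13 of 17 cases in the tendon-marker-rich, synaptic-marker-rich and remaining sections (14, 17 and 15 adjusted over the list alone), with camera adjusted p of 3.56e-12, 2.4e-14 and 6.5e-11. With an estimated correlation the adjusted p = 0.348, 0.439 and 0.362. Macrophage genes rose in 9 of 13, 11 of 13 and 13 of 14 (13 in each adjusted over the list alone), with medians of 3.54, 3.67 and 2.98 and camera adjusted p of 1.15e-08, 1.89e-09 and 3.74e-07. With an estimated correlation their adjusted p = 0.431, 0.441 and 0.494. Regenerating fibre genes rose in 6 of 10, 6 of 11 and 8 of 12 (9, 9 and 10 adjusted over the list alone), with medians of 3.47, 3.29 and 3.12 (camera adjusted p = 2.28e-07, 1.26e-05 and 7.02e-07, and adjusted p = 0.348, 0.439 and 0.352 with an estimated correlation). Erythroid genes had a median of 0.02 in tendon-marker-rich sections, with none past the threshold and camera leaning downward, and were lower in 4 of 5 synaptic-marker-rich and 5 of 5 remaining cases (5 and 5 adjusted over the list alone, camera adjusted p = 0.00135 and 0.00351, and adjusted p = 0.441 and 0.494 with an estimated correlation). Over whole muscles Hba-a1 lay at 3163 CPM in Ctr replicate 1 and 1.109e+04 CPM in Ctr replicate 2, so the size of the whole-muscle fall depends on Ctr replicate 2. Camera called 8 of 22, 7 of 21 and 10 of 24 lists that do not define regions, and 0 in any of them with an estimated correlation.

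The order of the sections carried structure in most lists. Neighbouring sections had more similar list scores than shuffled orders in 113 of 189 combinations of list and muscle (permutation test, one-sided, adjusted). Erythroid scores did so in 7 of 7 muscles, with correlations between neighbours of 0.61 to 0.97, and so did tendon, region-defining synaptic, Schwann cell, fast fibre and glycolysis scores. Macrophage, fibrotic matrix and slow fibre scores did so in 6 of 7 muscles. In DMD replicate 1 macrophage genes were 5.07 times as high, fibrotic matrix genes 2.96 times and proliferation genes 7.36 times as high in the last 20% as in the first 20% of the sections. The ratios were smaller in the other DMD muscles, 0.889, 0.958 and 0.602 in DMD replicate 2 and 1.85, 1.06 and 1.71 in DMD replicate 3. For erythroid genes this ratio was 0.183 and 0.291 in WT, 0.332 and 0.0714 in Ctr, and 0.166, 0.717 and 1.31 in DMD. Of the tendon-marker-rich sections, 100 and 100% lay in the second part of the order in WT, 72.7 and 72.7% in Ctr, and 58.3, 53.8 and 91.7% in DMD. Unevenness along the muscle was above Ctr in all 3 DMD muscles for 0 of the 19 lists with a mean of at least 1 count per thinned section in every muscle, of 26 measured. Of the 7 lists with fewer counts, 3 lay above Ctr in all 3 DMD muscles (satellite cell, bone, cartilage and skin, and region-defining synaptic genes). Of all these lists 0 passed an exact permutation test, two-sided, whose smallest p is 0.1 for 3 muscles against 2 and 0.0286 for 3 against 4.

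**Figure D4:**
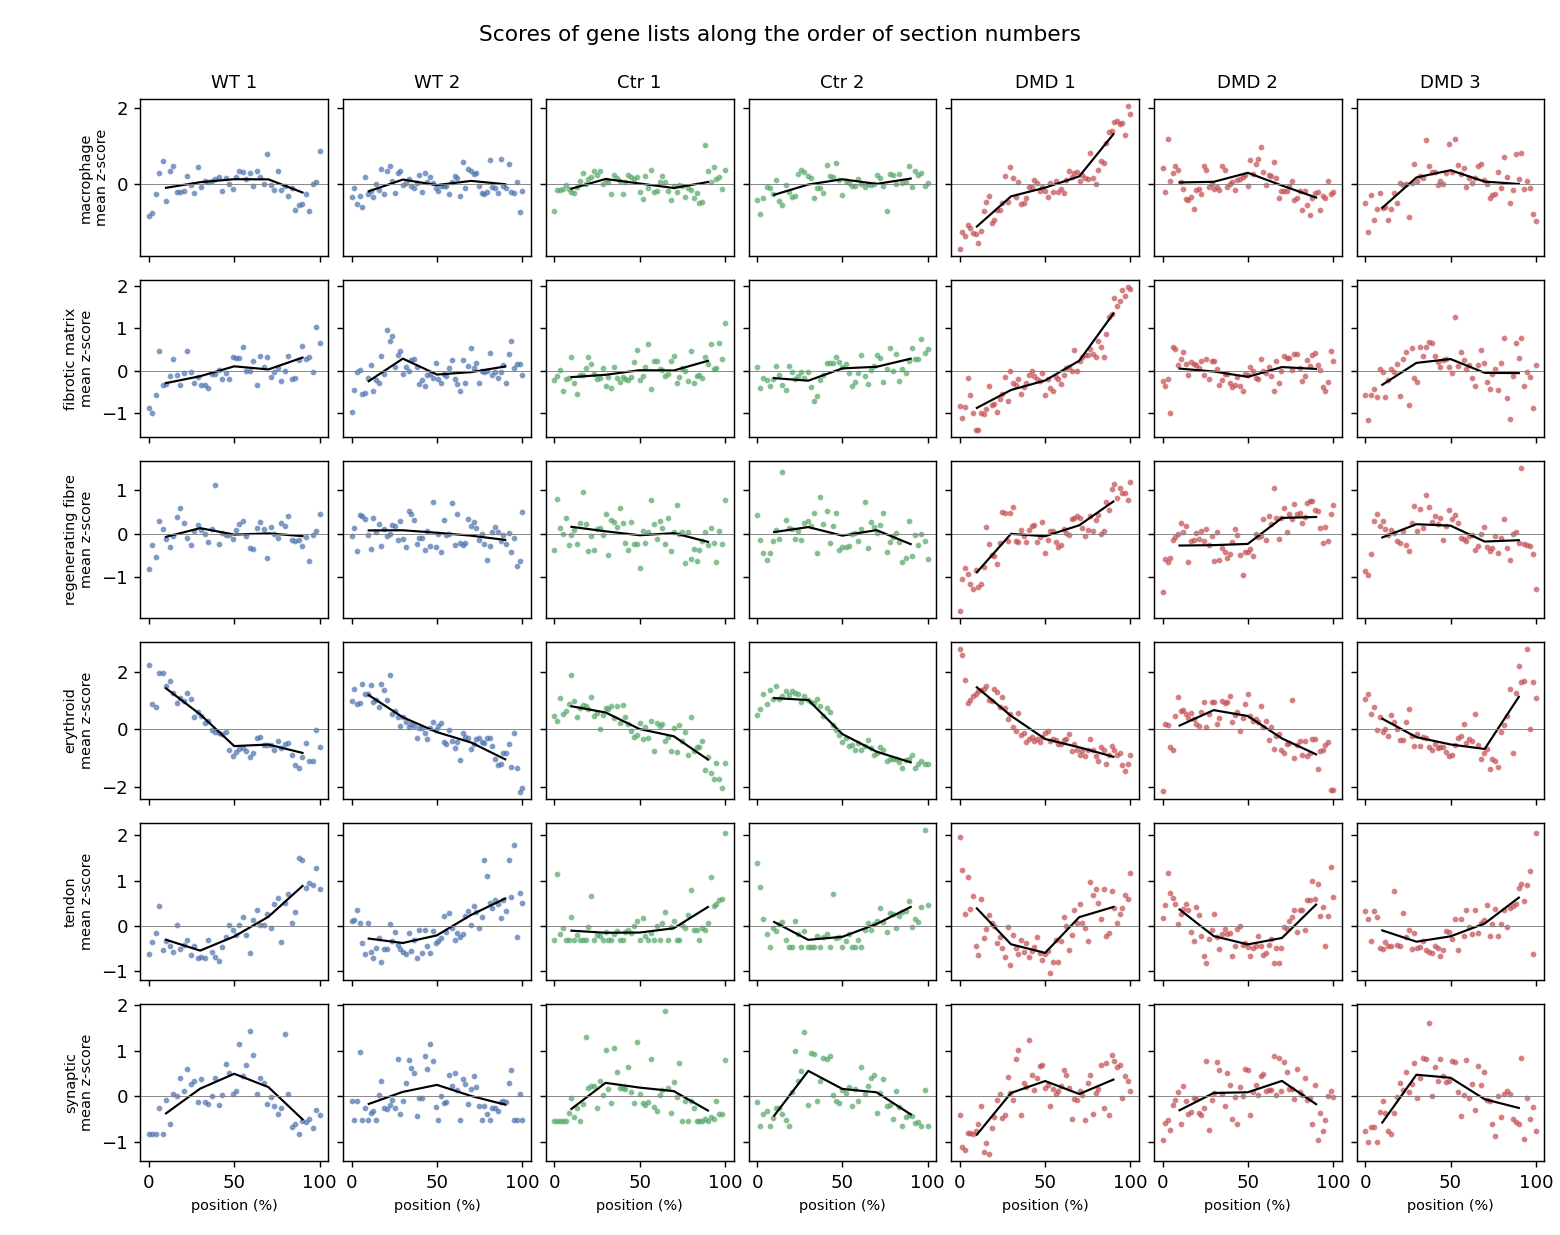
Mean z-score of 6 gene lists (macrophage, fibrotic matrix, regenerating fibre, erythroid, tendon and synaptic) against section position in percent, for the 7 muscles; points are sections and lines join the means of spans of 20%. In DMD replicate 1 the macrophage score rose along the order, with 5.07 times the level in the last 20% as in the first 20%.

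The genes named most often lie at these places on GRCm38. Lgals3 spans 14:47367751-47386160, Ctss 3:95526786-95556403, Ankrd1 19:36111961-36120099, Tnnt2 1:135836354-135852260, Col3a1 1:45311538-45349706 and Col1a1 11:94936224-94953042. Timp1 spans X:20870166-20874735, Mymk 2:27061636-27072179, Chrng 1:87204657-87212694, Chrna1 2:73563215-73580338, Comp 8:70373558-70382066 and Nos1 5:117781032-117958840. Myl3 spans 9:110741861-110769798, Pdk4 6:5483351-5496309, Fbxo32 15:58175879-58214932, Cdkn1b 6:134920401-134925513, Mb 15:77015487-77050670 and Myh2 11:67171027-67197517. Mss51 spans 14:20482867-20496901, Hbb-bt 7:103812524-103813996, Thbs4 13:92751590-92794818, Actc1 2:114047282-114053548 and Mbp 18:82475146-82585637. Nmrk2 spans 10:81198170-81202051, Actn2 13:12269426-12340760 and Prkar1a 11:109649405-109669656.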

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

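The tests of the matrix and tendon lists against WT, of the 4 genes Fbxo32, Trim63, Pdk4 and Acss1, of the genes called without Ctr replicate 2, and of the higher Ctr muscle were chosen after the result was seen. The region effect of Mss51 differed between groups by -1.27 on the log2 scale (DMD minus Ctr), and that of Hbb-bt by 1.53, each past the test of the difference itself. Outside the compared genes, the EGFP sequence counted in the WT tables held 33 counts in WT replicate 1 and 15 in WT replicate 2. The highest share of spike-in counts was 0.0145% in Ctr replicate 2 (95% interval 0.0138 to 0.0152%), and the highest share of counts outside the shared genes was 0.0186% in DMD replicate 2 (0.0178 to 0.0194%). No group had 4 to 10 muscles, so single muscles were not tested for lying far from their group.

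Matrix and tendon genes were higher in DMD than in Ctr, with list medians of 2.66 and 1.90. If the Ctr muscles had fewer tendon-bearing sections, both lists should lose their rise against WT. The fibrotic matrix list kept a median of 1.65 ± 0.26 against WT, which argues against this as the whole of the matrix difference in these muscles. The ± is over the genes of the list and not between muscles, and the list did not pass camera against WT with an estimated correlation. The tendon list had -0.56 ± 0.42, so for tendon genes a lower tendon content of the Ctr sections is a candidate explanation. A difference of the DMD muscles in tendon genes stays open as untested, as does the annotation or batch of the WT tables.

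Genes lower in DMD than in Ctr could reflect high values in Ctr replicate 1. Ctr replicate 2 was the higher Ctr muscle in 29.5 ± 1.66% of the 755 genes (223) and lay above all DMD muscles in 752. Without Ctr replicate 1 the 755 genes had a median of -0.99 ± 0.03 (against -1.16 with it). The genes had been chosen with both Ctr muscles in the fit, which favours these outcomes, so none tests the explanation. The 509 genes called lower without Ctr replicate 2 had a median of -0.87 ± 0.05 against Ctr replicate 2 (-1.52 against replicate 1) with the same DMD muscles in both, and Fbxo32, Trim63, Pdk4 and Acss1, picked for high values in Ctr replicate 1, had -1.02 ± 0.24 (against -2.64), so neither value tests the explanation. High values in Ctr replicate 1 stay open as a cause, and so does the DMD label itself.

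The rise of Mss51 and the fall of Hbb-bt at tendon-marker-rich sections were smaller in DMD than in Ctr. Marker-rich sections at both ends of the DMD muscles could cause this, and with only the sections of the later part of the order Mss51 had -1.54 ± 0.21 (adjusted p = 0.000479) and Hbb-bt 1.498 ± 0.376 (adjusted p = 0.38), against -1.27 ± 0.19 and 1.53 ± 0.25 with all marker-rich sections. The sizes did not shrink by more than their error, which argues against this explanation, but the call of Hbb-bt ended, as fewer sections gave a wider error. Over all alternatives the adjusted p ran from 1.79e-05 to 0.997 for Mss51 and from 1.79e-05 to 1 for Hbb-bt. For Hbb-bt a gradient of blood along the order stays open, since erythroid genes had neighbour correlations of 0.61 to 0.97, and a difference of the DMD muscles stays open as untested.

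For the tendon-region calls 1 of 64 swaps of the sums within muscles gave as many genes, the real arrangement itself, which is the smallest share that 64 swaps allow. The real arrangement thus stood highest, but chance is not excluded by this. It gave 187 genes, and the others gave 177 at most. That 177 came from swapping DMD replicate 3 alone, and swapping DMD replicate 2 gave 133, DMD replicate 1 gave 98 and all 3 DMD muscles 54, while swapping 1 Ctr muscle gave 10 or 11 and WT replicate 2 gave 0. This points to a structure of the samples, in which the calls rest more on the WT and Ctr muscles than on DMD. For the synaptic region 3 of 64 swaps gave as many, with 1 real and at most 1 other. Swapping Ctr replicate 2 alone gave as many, so that count of 1 does not tell the real sections from these swaps. For DMD against WT and Ctr joined, 1 of 35 splits gave as many, the real one, with 1834 real and 1 at most in the others. For the tendon-region effect with WT and Ctr joined it was also 1 of 35, with 14 real and 4 at most in the others. That share is the smallest that 35 splits allow (0.0286), and every other split mixes DMD with other muscles, which widens the spread within groups. The real split stood highest in both, which makes chance less likely but does not exclude it.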

How the results depend on the processing

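The alternatives with mitochondrial genes left out, and with thinned sections for the region results, were tests chosen after the result was seen. Of the values for single genes, 4548 kept direction and side of the threshold, 809 lost and 57 gained the call, and 2 reversed, both with WT and Ctr joined: Cilp2 (DMD against Ctr, -0.067) and Pax7 (remaining sections, -0.12). Of the counts, 46 stayed within 1.5 times and 79 moved. The causes were not tested, except that fewer genes, counts or muscles enter some alternatives by construction.

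Where the count for DMD against Ctr was 1740, it was 377 with a mean of at least 20 CPM, 2999 with no filter, 621 with thinned sections, 683 with only the 2 groups in the fit, and 56 to 3425 without 1 of the compared muscles. For DMD against WT it was 429, 3208 and 543 under the first 3 of these, and 68 to 3595 without 1 muscle. For WT against Ctr it was 76 with a mean of at least 20 CPM, 475 with the DESeq2 Wald test, 860 with no filter, 586 with only the 2 groups, and 2 to 97 without 1 muscle, and its share of higher genes moved from 46.0% to 60.3% with thinned sections and 27.8% without Ctr replicate 2. The share of called genes that were higher moved from 56.6% to 64.3% with WT and Ctr joined and 65.6% with no filter for DMD against Ctr, from 54.4% to 67.8% with no filter for DMD against WT, and from 56.1% to 65.0% with the top 10% of sections in tendon-marker-rich sections (69.9% with WT and Ctr joined). Without Ctr replicate 1 or 2 it fell to 28.6 or 46.4% for DMD against Ctr, 23.1 or 45.0% in remaining, 40.0 or 46.1% in tendon-marker-rich and 33.3 or 46.7% in synaptic-marker-rich sections, and without WT replicate 1 or 2 to 15.4 or 20.6% for DMD against WT.

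For the tendon region the share of higher genes moved from 26.2% to 42.5% with DESeq2 size factors and 45.1% with a mean of at least 20 CPM, and the count was 86 with the top 10% of sections, 52 with thinned sections and 68 to 182 without 1 muscle. For the synaptic region it was 2 with DESeq2 size factors (50% higher), 1 with a mean of at least 20 CPM and 3 with the top 10% (all higher, where the called gene was lower), 0 in edgeR with a section minimum 2 times as high or thinned sections, and 0 to 2 without 1 muscle. For the difference of the tendon-region effect it was 8 with a mean of at least 20 CPM, 0 with the top 10%, 1 with the higher section minimum, 14 with WT and Ctr joined, 4 with thinned sections and 0 to 10 without 1 muscle, and for the synaptic-region effect 0 to 0. Inside tendon-marker-rich, synaptic-marker-rich and remaining sections it was 230, 310 and 351 with a mean of at least 20 CPM, 326 with the top 10% in the first, and 30 to 1364, 45 to 1683 and 52 to 2730 without 1 muscle.

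With replicate number as a block the counts were 3890, 4063 and 798 for the whole-muscle comparisons and 1663, 2088 and 3178 inside the regions. Only DMD has a replicate 3, so the block gives DMD replicate 3 a term of its own and takes it out of the comparison. Leaving that muscle out gave 3425 calls against Ctr and 3595 against WT, so the block counts do not show a pairing. The labels do not say whether the same replicate number pairs the muscles, so whether this block is right stays open. The 14 lists called for DMD against Ctr were 0 with an estimated correlation and 8 with fry. Unevenness was above Ctr in all DMD muscles for 1 list with the smaller thinning total and for 1 without the 10% of sections with the lowest totals. The expression filter left 13746 of 53083 genes in whole muscles, 11767 between regions and 8600 inside tendon-marker-rich sections, and the others were not tested.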

Other observations

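The test of response genes was chosen after the result was seen, and 13 other genes of its list had been looked at before, so they were left out. A hypothesis was that Ctr replicate 1 carried a glucocorticoid or fasting response, which might raise Pdk4 (306 against 20.5 CPM in Ctr replicate 2), Fbxo32 (1183 against 234) and Trim63 (494 against 78.8). Of 17 response genes whose values had not been seen, 9 had their highest value of the 7 muscles in Ctr replicate 1, the 99.65 percentile among 10000 random lists matched on mean expression (median 4). The labels give no treatment, feeding or time of sampling, so this stays a hypothesis.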
